A study of Mus musculus with 27 samples.

How the data were processed

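RNA was sequenced from 27 libraries of perfused and dissociated mouse lung, either sorted by flow cytometry or left as total lung cells. Libraries were prepared with TruSeq chemistry. Per the submitters' processing notes, the authors called bases with CASAVA 1.8.2, aligned reads to the mouse genome (mm10, GRCm38) with TopHat2, and estimated expression with Cufflinks and Cuffdiff. The deposited table holds FPKM for 16024 rows, each a gene symbol, and all 27 of its columns were matched to a library by their titles. Reads and fragment counts were not analysed here, so no counting interval is given for any value. A relative depth of each library was read from the spacing of its values under 0.2 FPKM, in windows of 0.02 on the log2 scale.

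Libraries were grouped by cell preparation and by tumour or wild-type lung, as their cell type and source labels state. FPKM were used as deposited, raised by 1 and put on the log2 scale. Genes with at least 1 FPKM in at least 2 of the libraries compared were tested. Tumour was compared with wild-type within each preparation by limma 3.58.1 in R 4.3.3, with an intensity trend and empirical Bayes moderation, and p values were adjusted by Benjamini and Hochberg. An adjusted p under 0.05 was the threshold. An interaction term tested whether the tumour effect differed between pairs of myeloid populations, and overlaps of calls were tested by an exact hypergeometric test. Genes were counted as shared by all 3 myeloid populations if called the same way in each.

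A set of 41 gene lists was tested with camera at its preset correlation of 0.01, in each comparison where at least 5 members passed the filter. Of the 799 list entries, 714 were found in the table. Camera was rerun with a correlation estimated per list. Results of lists are given where the list passed, for the interferon-stimulated list in every preparation, and for some lists that did not pass, which the text says in each case.

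Genes named in the text followed a rule. In each comparison it took the 8 genes with the largest rise and the 8 with the largest fall among those that passed, whose groups did not overlap and whose higher group averaged at least 5 FPKM, leaving out predicted genes, small RNAs, olfactory receptors, pseudogenes and immunoglobulin and T cell receptor segments. It added, for every list that passed, the 3 members with the largest change among those that passed with a mean of at least 5 FPKM, or the highest member if none passed. Sort markers were added in every comparison and the HKP1 driver genes in epithelial cells. For interactions it took the 5 largest differences each way. Not every gene of the rule is written out, and some are not reported here. Genes listed at exactly 0 in all libraries of a group, while the other group averaged at least 5 FPKM, are reported as such, without a fold. Gene positions came from GENCODE M21 on GRCm38. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

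Alternatives changed one choice at a time. They were a pseudocount of 0.1 or 5, no filter, a filter of 5 FPKM, quantile normalization, upper-quartile scaling, a fit of all 10 groups together, robust empirical Bayes, a block for the replicate number, each library left out in turn and the estimated correlation. A pair was added after the data were seen: leaving out genes listed at 0 in a whole group, and leaving out genes at least 20 times higher in another sorted population.

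The tests were also tested on simulated data, after they had been run on the real values. With 200 changed genes planted in the measured spread, limma recovered 77% of changes of 1 on the log2 scale in macrophages, 84% in neutrophils, 69% in epithelial cells and 84% in total lung cells, with 8, 10, 10 and 8 false calls. In monocytes it recovered 0% of changes of 1 and 24% of changes of 2. The planted genes averaged at least 5 FPKM in WT libraries, and each comparison was simulated in a single draw. Recovery of genes with lower WT levels was not measured. The interactions gave 39 false calls of 163 for macrophages against monocytes, 17 of 186 for macrophages against neutrophils and 51 of 185 for monocytes against neutrophils. Simulated genes varied independently of each other, so these runs could not show false list calls caused by correlated genes. Camera with the preset correlation called both shifted lists in each of the 5 preparations and 1 other list in macrophages. With an estimated correlation it called both in neutrophils and total lung cells, 1 in macrophages and none in monocytes or epithelial cells.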

Results

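Gene expression was measured by RNA sequencing in 27 libraries from mouse lung. They fell into 10 groups: 5 cell preparations, each from tumour-bearing lungs and from wild-type (WT) lungs. Tumours grew from HKP1 cells, a mouse lung cancer line without p53, injected into the tail vein, and tumour lungs were taken between day 20 and day 25. Macrophages were sorted as CD11c+CD11b+ cells from tumour lung (n = 3) and as CD11c+CD11b- cells from WT lung (n = 2), so that these gates differ in CD11b itself. Monocytes were CD11b+Ly6C+ (n = 2 and 2), neutrophils CD11b+Ly6G+ (n = 3 and 3) and epithelial cells Epcam+CD11b-CD11c- (n = 3 and 3). Unsorted total lung cells made up the last pair of groups (n = 3 and 3). The labels do not state which libraries came from separate animals, so p-values measure the spread between samples.

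The deposited values were FPKM, fragments scaled to transcript length and to the mapped fragments of the library. Read counts were not analysed here, so the depth of each library was known only in relative terms. The spacing of the lowest FPKM values put the depth of the libraries between 0.831 and 1.58 times that of tumour macrophage replicate 1. Tumour epithelial libraries lay at 1.25 to 1.58 and WT epithelial libraries at 0.831 to 0.962. The spacing chosen was barely ahead of the next in some libraries, with 19 genes against 16 in WT epithelial replicate 9, so these depths are rough. Between 8560 and 11420 genes reached 1 FPKM per library. Pearson correlations of log2 values between replicates of a group ranged from 0.964 in tumour epithelial cells to 0.996 in tumour neutrophils.

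Itgam, Itgax and Epcam were expressed in the populations named here that were sorted for them. No value is given for the Ly6c or Ly6g genes, so those parts of the monocyte and neutrophil gates were not checked. Itgam, which encodes CD11b, averaged 127 ± 13 FPKM in CD11b+ tumour macrophages (mean ± SD, n = 3) and 1.30 ± 0.144 in CD11b- WT macrophages (n = 2), a difference set by the sort. In neutrophils it stood at 346 ± 44.6 in tumour and 349.5 ± 10.3 in WT libraries (n = 3 each). Itgax, which encodes CD11c, reached 458 ± 6.12 FPKM in tumour and 347 ± 3.28 in WT macrophages. Epcam reached 91.1 ± 6.24 FPKM in tumour epithelial cells and 87.1 ± 8.70 in WT epithelial cells. WT macrophages also carried Epcam at 45.3 ± 3.27 FPKM, against 4.50 ± 2.22 in tumour macrophages. Ptprc, the leukocyte antigen CD45, was at 18.0 ± 3.75 and 24.8 ± 11.2 FPKM in tumour and WT epithelial cells, and at 139 ± 7.52 in tumour macrophages.

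Several highly expressed genes were listed at exactly 0 in every library of a group, and no fold is given for them. Ctsd and Psap, lysosomal genes, were listed at 0 in the 3 tumour macrophage libraries, where the WT libraries averaged 2525 ± 86.0 and 1835 ± 43.7 FPKM (n = 2). The alarmin gene S100a9 was listed at 0 in WT neutrophils, and Il1b was listed at 0 in tumour neutrophils. Sftpc was listed at 0 in the 3 WT total lung libraries, although sorted WT neutrophils carried it at 968 ± 701 FPKM (n = 3).

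Macrophages of tumour lung were compared with those of WT lung, and the C1q genes were among their largest rises. C1qa, C1qb and C1qc encode the 3 chains of complement C1q. They rose from 5.46 ± 4.31, 4.72 ± 5.79 and 4.06 ± 4.97 FPKM in WT libraries (mean ± SD, n = 2) to 1409 ± 259, 1654 ± 311 and 1125 ± 214 FPKM in tumour libraries (n = 3). Spp1, which encodes osteopontin, rose from 334 ± 86.5 to 6811 ± 3462 FPKM, and the elastase gene Mmp12 from 14.6 ± 15.2 to 737 ± 81.0. Genes typical of resident alveolar macrophages fell: Fabp1, a fatty acid carrier, from 344 ± 18.2 to 4.08 ± 2.0 FPKM and the lipid droplet gene Cidec from 185 ± 20.2 to 1.87 ± 0.201. These populations were sorted on opposite CD11b status, so tumour and gate changed together.

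By limma, 2050 of 10119 genes were higher and 1788 lower in tumour macrophages. The larger share was lower instead after quantile normalization (1801 higher, 2178 lower) and upper-quartile scaling (1821 and 2157). The C1q genes lie together on chromosome 4 of GRCm38, from position 136880129 at C1qb to 136898803 at C1qa. Their log2 changes were 7.94 (C1qa), 8.67 (C1qb, SE 0.67, adjusted p = 0.000148) and 8.26 (C1qc). Other large rises were Pla2g7, a phospholipase (log2 change 6.45), the chemokine gene Ccl4 (6.17), Mfge8, a bridge for apoptotic cell uptake (6.14), and Thbs1, thrombospondin (6.12). Other large falls were Krt79 (-5.76), the neuropeptide gene Gal (-5.48) and Coro6 (-5.33). Ifnb1, which encodes interferon beta, was listed at 0 in both WT libraries and stood at 267 ± 7.57 FPKM in the 3 tumour libraries. Without WT replicate 1 the counts were 1105 and 673, and without WT replicate 2 they were 1160 and 685.

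Of the lists fixed before the data were examined, 11 of 36 rose and 4 fell by camera in macrophages. By adjusted p, though not by median change, interferon-stimulated genes led, with 22 of 24 members higher and none lower. Their median log2 change was 1.75 (adjusted p = 3.23e-12, and adjusted p = 0.236 with an estimated correlation). Rsad2 rose from 0.219 ± 0.0281 to 83.6 ± 15.5 FPKM, Ifit1 from 0.305 ± 0.00311 to 69.2 ± 6.45 and Ifit2 from 0.746 ± 0.00648 to 79.9 ± 6.01. Monocyte-derived macrophage markers rose in 16 of 20 members (adjusted p = 2.42e-08; adjusted p = 0.332 with an estimated correlation), among them Pf4, from 2.82 ± 1.71 to 73.5 ± 5.43 FPKM. Alveolar macrophage markers fell in 14 of 18 members (median log2 change -2.75, adjusted p = 3.38e-09; adjusted p = 0.255 with an estimated correlation). They included Il18, from 316 ± 11.1 to 23.2 ± 6.94 FPKM. These 3 lists had 22, 16 and 14 called members in the same directions when adjusted over the list alone.

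Chemokines rose in 18 of 20 members (adjusted p = 6.04e-08) and inflammatory mediators in 15 of 20 (adjusted p = 4.29e-06). With an estimated correlation these lists had an adjusted p = 0.332 and an adjusted p = 0.236. Il1b, interleukin 1 beta, rose from 42.9 ± 3.28 to 1326 ± 214 FPKM and Ptgs2, an inducible cyclooxygenase, from 2.06 ± 0.53 to 149 ± 22.6. The list of immune regulation and alternative activation rose in 15 of 21 members (adjusted p = 2.02e-05; adjusted p = 0.332 with an estimated correlation). Arg1, which encodes the arginine-degrading enzyme arginase 1, rose in it from 22.3 ± 31.2 to 137 ± 48.7 FPKM (adjusted p = 0.0491), but lost its call in 9 of 16 alternatives. Without tumour replicate 1, 2 or 3 or WT replicate 1 its adjusted p was 0.0765, 0.101, 0.0679 or 0.0581. MHC class I rose in 8 of 12 members and class II in 9 of 13 (adjusted p = 0.00124 and 0.00427; adjusted p = 0.332 and 0.646 with an estimated correlation). Cd74, the class II invariant chain, rose from 1856 ± 209 to 6742 ± 2707 FPKM, a call that ended without WT replicate 1 or 2 (adjusted p = 0.0622 and 0.0856). The rising members of these 5 lists, adjusted over the list alone, numbered 18, 15, 16, 8 and 9.

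Glycolysis rose in 12 of 18 members, hypoxia and angiogenic factors in 10 of 20, matrix proteases and inhibitors in 17 of 24 and complement in 10 of 13. Their adjusted p values were 0.000856, 0.000112, 0.000123 and 0.000929. With an estimated correlation hypoxia had an adjusted p = 0.236, glycolysis an adjusted p = 0.456, and the other lists an adjusted p = 0.332. Vegfa, a vascular growth factor, rose from 7.99 ± 0.348 to 168 ± 11.1 FPKM, the hexokinase gene Hk2 from 15.7 ± 0.351 to 63.4 ± 10.1 and the collagenase activator Mmp14 from 2.52 ± 0.0404 to 119 ± 22.8. Cell cycle genes fell in 22 of 38 members (median log2 change -0.64, adjusted p = 1.20e-06; adjusted p = 0.589 with an estimated correlation). Rrm2, a subunit of the enzyme that makes DNA precursors, fell from 20.8 ± 0.855 to 6.08 ± 1.60 FPKM. Markers of other lung cells moved as well: endothelial markers fell in 16 of 18 members (adjusted p = 2.67e-08; adjusted p = 0.332 with an estimated correlation) and club cell markers in 2 of 6 (adjusted p = 0.023; adjusted p = 0.425 with an estimated correlation). The club cell call ended in the fit of all 10 groups (adjusted p = 0.226). Adjusted over the list alone, the members numbered 12, 14, 17 and 10 among those higher, and 23, 17 and 4 among those lower.

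In monocytes Spp1 and the surfactant gene Sftpc were among the largest differences, but the replicates lay far apart. Spp1 stood at 905 ± 866 FPKM in tumour and 23.6 ± 9.17 in WT libraries (mean ± SD, n = 2 each), and Il1b at 3275 ± 2676 against 189.6 ± 103. Cd74 stood at 5188 ± 487 against 2173 ± 189 FPKM, and the apolipoprotein gene Apoe at 2328 ± 833 against 918 ± 208. Sftpc, the surfactant gene of alveolar type II cells, stood at 11.8 ± 5.69 FPKM in tumour and 1005 ± 1097 in WT monocytes.

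No single gene of 10366 passed in monocytes (limma, lowest adjusted p = 0.0911). At an unadjusted p under 0.05, 744 genes were higher and 815 lower, where chance gives 259 each way. Without tumour replicate 5, where a lone tumour library was assumed to vary like the WT libraries, 161 genes were higher and 149 lower. The 2 WT libraries differed in S100a8, at 666 FPKM in replicate 4 and 10.9 in replicate 3, and the cause was not tested.

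By camera, 13 of 36 lists were higher and 8 lower in tumour monocytes, and each of these had an adjusted p of at least 0.527 with an estimated correlation. The immune regulation list (22 members, median log2 change 1.64) and MHC class II (13 members, 1.17) were higher at an adjusted p = 1.20e-08 each. Chemokines followed (22 members, 1.62, adjusted p = 1.26e-07), then glycolysis (18 members, 0.64, adjusted p = 1.68e-06) and monocyte-derived macrophage markers (20 members, 1.22, adjusted p = 3.18e-06). Inflammatory mediators (adjusted p = 0.000223), matrix proteases and inhibitors (0.00345) and alveolar macrophage markers (0.0131) were also higher. Cell cycle, mesenchymal, MAPK output, immediate early and unfolded protein response lists were higher at adjusted p values of 0.0314 to 0.0492, and each lost its call in 3 or more alternatives. Without WT replicate 3 the last 4 were not called and the cell cycle list was lower instead (adjusted p = 0.00826). The calls adjusted over the list alone were 17 immune regulation genes, 9 MHC class II genes, 13 chemokines and 10 monocyte-derived macrophage markers higher, with 1 immune regulation gene and 1 chemokine lower. Interferon-stimulated genes were not shifted in monocytes (25 members, median log2 change -0.05, adjusted p = 0.647).

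Endothelial markers were lower in tumour monocytes (19 members, median log2 change -1.97, adjusted p = 4.51e-15; adjusted p = 0.527 with an estimated correlation), and adjusted over the list alone all 19 were called. Among them Ramp2, a receptor partner in endothelium, stood at 43.4 ± 33.9 FPKM against 163 ± 79.9 in WT libraries. Alveolar type II markers were lower (14 members, adjusted p = 3.18e-06), as were matrix and fibroblast genes (0.00379), B cell markers (0.00988), non-classical monocyte markers (0.0118), club cell markers (0.0175), alveolar type I markers (0.0293) and classical monocyte markers (0.0413). Of these, type II markers alone kept the call in every alternative that kept the preset correlation. Without tumour replicate 4, matrix and fibroblast genes, non-classical and classical monocyte markers and, among the higher lists, alveolar macrophage, mesenchymal and MAPK genes were no longer called. Without WT replicate 3 the first 3 and the type I markers were not, and without WT replicate 4 club and B cell markers were not (adjusted p = 0.236 and 0.357).

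Neutrophils of tumour lung had more Il23a and Ltc4s transcripts and fewer Camp, Slpi and Rsad2 transcripts than those of WT lung. Il23a, which encodes the p19 chain of interleukin 23, rose from 10.1 ± 1.83 FPKM in WT to 454 ± 47.2 in tumour libraries (mean ± SD, n = 3 each). Ltc4s, leukotriene C4 synthase, rose from 2.41 ± 0.889 to 145 ± 25.1 FPKM. Camp, the antimicrobial peptide cathelicidin, fell from 197 ± 90.8 to 5.19 ± 2.57 FPKM, and Slpi, a protease inhibitor of granules, from 2309.8 ± 244 to 587 ± 141. Rsad2, which rose in tumour macrophages, fell here from 99.2 ± 16.7 to 23.9 ± 10.9 FPKM.

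In neutrophils limma called 3115 genes higher and 2409 lower of 9349, against 2700 and 2694 after upper-quartile scaling. Of those called, 725 rose and 857 fell by at least 1 on the log2 scale. The median gene lay 0.11 higher on the log2 scale in tumour neutrophils, against 0.05 after quantile normalization and 0.03 after upper-quartile scaling, and changes are to be read relative to that shift. Il23a, on chromosome 10 from 128296139 to 128298752, changed by 5.36 on the log2 scale (SE 0.14, adjusted p = 6.22e-08). Ltc4s changed by 5.44, the membrane protein gene Ms4a6d by 4.95 and Rcan1, a calcineurin regulator, by 4.82. C1qa, C1qb and C1qc, which rose in tumour macrophages, changed by 2.47, 2.90 and 2.41 in neutrophils. In the fit of all 10 groups, 9 of 16 monocyte-derived macrophage markers were higher and 2 lower. Their list did not pass by camera in that fit (adjusted p = 0.519). Whether RNA of other cells added to these rises was not tested. The chemokine genes Ccl3, Cxcl10 and Cxcl1 rose by 2.60, 2.95 and 2.29, Ccl3 from 1206 ± 231 to 7272 ± 1096 FPKM. S100a8, chosen after its values were seen because its partner S100a9 was listed at 0 in WT libraries, fell from 22794 ± 1376 to 10299 ± 732 FPKM (log2 change -1.15, adjusted p = 0.00067). In tumour libraries S100a9 stood at 15799 ± 2305 FPKM. Il1r2 and Hdc were likewise listed at 0 in WT, and Il1b, Ccrl2 and Plek in tumour neutrophils, where the other 3 libraries averaged 1732 to 6902 FPKM.

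By camera, 3 of 37 lists rose and 9 fell in neutrophils, each with an adjusted p = 0.696 with an estimated correlation. Oxidative phosphorylation rose in 20 of 28 members (median log2 change 0.62, adjusted p = 4.18e-05), and Atp5o, an ATP synthase subunit gene, went from 16.9 ± 1.61 to 49.0 ± 9.15 FPKM. Chemokines rose in 10 of 16 members (adjusted p = 0.00614), a call that ended in the fit of all 10 groups (adjusted p = 0.0669). Inflammatory mediators did not pass (8 of 19 members higher and 3 lower, adjusted p = 0.201). Cell cycle genes rose in 15 of 27 (adjusted p = 0.0231), a call that ended without tumour replicate 6 (adjusted p = 0.0504), in the fit of all 10 groups (adjusted p = 0.272) and when only genes of at least 5 FPKM were kept (adjusted p = 0.978). Interferon-stimulated genes fell in 15 of 24 members and rose in 2 (median log2 change -0.72, adjusted p = 0.00351). Isg15, a ubiquitin-like interferon product, fell from 411 ± 51.8 to 119 ± 47.2 FPKM. Phagocyte oxidase and antimicrobial genes fell in 9 of 12 members (median -1.13, adjusted p = 0.0038), with Pglyrp1, a bacterial wall binding protein, going from 612 ± 69.3 to 183 ± 55.0 FPKM. Mature neutrophil markers did not pass (16 members, adjusted p = 0.647), with a median log2 change of -0.26 and a mean of 1.75 that rested on members listed at 0 in WT libraries. With members listed at 0 in a group left out, an alternative added after the data were seen, the list was lower (adjusted p = 0.0151). Non-classical monocyte markers fell in 6 of 10 members (adjusted p = 0.0231), among them Ace, a call that ended in the fit of all 10 groups (adjusted p = 0.0849), without a filter (0.0583) and when genes far higher in another population were left out (0.0504). These lists had, adjusted over the list alone, 21, 10 and 16 members higher and 15, 9 and 6 lower.

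Transcripts of other lung cells fell along with these lists. Endothelial markers fell in 17 of 18 members, alveolar type II markers in 12 of 16, type I markers in 7 of 10 and matrix and fibroblast genes in 18 of 22. Their adjusted p values were 2.13e-07, 2.24e-05, 0.00637 and 5.90e-05. B cell markers fell in 12 of 12 (median log2 change -2.34, adjusted p = 2.25e-05) and T cell markers in 7 of 15 (adjusted p = 0.0198). The T cell call ended without tumour replicate 8 (adjusted p = 0.0512) or WT replicate 7 (adjusted p = 0.121), and in the fit of all 10 groups (adjusted p = 0.0517). Scgb1a1, the club cell secretoglobin, was at 778 ± 523 FPKM in WT neutrophils and 12.4 ± 6.14 in tumour neutrophils. Sftpc went from 968 ± 701 to 20.3 ± 14.3 FPKM, and Cd79a, a B cell receptor component, from 77.6 ± 17.2 to 12.3 ± 9.90. Adjusted over the list alone, the members lower were 17, 13, 7, 18, 12 and 7 in the order given.

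Epithelial cells of tumour lung had higher levels of cell cycle genes and of several genes that were under 3 FPKM in WT epithelium. Dmbt1, a mucosal scavenger receptor, rose from 0.381 ± 0.12 FPKM in WT to 360.1 ± 211 in tumour libraries (mean ± SD, n = 3 each), and Tff1 and Tff2, trefoil peptides of gastric mucus, from 0.0811 ± 0.141 and 2.27 ± 3.38 to 201 ± 149 and 577 ± 373. Cdkn2a, a cell cycle inhibitor locus on chromosome 4 from 89274471 to 89294653, rose from 0.0965 ± 0.0433 to 69.5 ± 34.2 FPKM. Birc5, a mitotic gene, rose from 1.8 ± 1.86 to 19.9 ± 5.86. Endothelial genes fell, with the caveolar diaphragm gene Plvap going from 47.9 ± 23.6 to 4.40 ± 2.91 FPKM.

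Limma called 1765 of 11823 genes higher and 1051 lower in tumour epithelial cells. Dmbt1 changed by 7.85 on the log2 scale (SE 0.41, adjusted p = 0.000382), Tff2 by 7.78, Tff1 by 7.28, Lgals2, a galectin, by 7.07 and the tight junction gene Cldn2 by 6.60. Spp1 rose from 55.6 ± 87.8 to 2419 ± 1316 FPKM (adjusted p = 0.0147), a call that ended without tumour replicate 9 (0.0628) or WT replicate 8 (0.0666). Trp53, which encodes p53, stood at 12.6 ± 1.90 against 17.6 ± 0.204 FPKM in WT (adjusted p = 0.0576; 0.0308 and called lower without tumour replicate 10). The largest falls were the methyltransferase gene Inmt (-3.83), the paraoxonase gene Pon1 (-3.73) and Cst8 (-3.28). Without WT replicate 8 or 10 none of these 3 was called (adjusted p = 0.0609 to 0.0844), nor was Plvap (0.0668 and 0.0541). Without tumour replicate 9 Pon1 and Cst8 were not called (0.0688 and 0.0921), and without WT replicate 9 Cst8 was not (0.0572). Scd1 was listed at 0 in tumour and Sftpa1 and Slc34a2 in WT libraries. The counts leaned on single libraries: without tumour replicate 9 they were 386 and 104, without tumour replicate 11 they were 715 and 286, and without tumour replicate 10 they were 2420 and 1795. Leaving out WT replicate 8, 9 or 10 gave 499, 1111 or 755 genes higher and 129, 524 or 180 lower.

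By camera, 11 of 37 lists rose and 8 fell in epithelial cells. Cell cycle genes rose in 37 of 39 members (median log2 change 1.73, adjusted p = 2.59e-18; adjusted p = 0.504 with an estimated correlation). Ccnb2, a mitotic cyclin, went from 1.33 ± 0.607 to 15.4 ± 4.14 FPKM. Mesenchymal transition genes rose in 14 of 23 members (adjusted p = 2.86e-05), among them fibronectin, Fn1, from 12.3 ± 4.45 to 207 ± 102 FPKM, and the chromatin factor gene Hmga2, from 0.12 ± 0.0959 to 15.6 ± 9.29. MAPK output genes rose in 9 of 21 members (adjusted p = 0.0322; not called without WT replicate 9 at 0.0597 or with the filter of 5 FPKM at 0.125), with Etv4, a transcription factor of that pathway, going from 0.787 ± 0.416 to 14.1 ± 6.62 FPKM. Chemokines rose in 12 of 20 members (adjusted p = 0.000167), led by the neutrophil attractant Cxcl5, from 0.0545 ± 0.0331 to 29.5 ± 15.0 FPKM. The last 3 lists also had an adjusted p = 0.504 with an estimated correlation. In the 4 lists 37, 14, 11 and 12 members were called higher when adjusted over the list alone.

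Glycolysis rose in 8 of 18 members, oxidative phosphorylation in 3 of 28, interferon-stimulated genes in 10 of 24, inflammatory mediators in 10 of 17, immune regulation in 9 of 19 and matrix proteases in 13 of 23. Their adjusted p values ran from 0.000226 for matrix proteases to 0.013 for oxidative phosphorylation, and with an estimated correlation each had an adjusted p of 0.504 to 0.53. Mmp13, a collagenase, went from 0.027 ± 0.0219 to 19.8 ± 10.4 FPKM. Markers of alveolar macrophages rose with them, in 11 of 18 members (median log2 change 2.18, adjusted p = 1.63e-05; adjusted p = 0.504 with an estimated correlation). Marco, a macrophage scavenger receptor, stood at 21.6 ± 16.7 FPKM in tumour and 0.619 ± 0.846 in WT epithelial libraries, a call that ended without WT replicate 8 or 10 (adjusted p = 0.0637 and 0.0523). The alveolar macrophage list was lower in sorted tumour macrophages, and which cells carried its members in epithelial libraries was not tested. Inflammatory mediators lost their call when genes far higher in another sorted population were left out (adjusted p = 0.146), an alternative added after the data were seen. Oxidative phosphorylation lost its call with a replicate block (adjusted p = 0.0681). Adjusted over the list alone, the members higher were 8, 0, 13, 11, 12, 14 and 14 in the order given.

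Endothelial markers fell in 18 of 19 members (median log2 change -2.68, adjusted p = 8.69e-11), B cell markers in 10 of 11 (adjusted p = 2.60e-06), cholesterol synthesis in 10 of 20 (adjusted p = 0.000217), alveolar type I markers in 6 of 14 (adjusted p = 0.00131) and MHC class II in 3 of 12 (adjusted p = 0.00451). These 5 lists had an adjusted p = 0.504 with an estimated correlation. Insig1, a sterol sensor partner, went from 97.8 ± 1.35 to 40.7 ± 10.9 FPKM and Hopx, a type I cell gene, from 75.9 ± 10.8 to 27.6 ± 6.10. T cell markers fell in 2 of 16 members (adjusted p = 0.0384) and ciliated cell markers in none of 18 (adjusted p = 0.0444), and Tppp3, a ciliated cell gene, stood at 159 ± 116 against 293 ± 166 FPKM. Alveolar type II markers had a median log2 change of -1.40 and 1 of 14 members lower (adjusted p = 0.0374; adjusted p = 0.727 with an estimated correlation), while their mean change was 0.18 because 2 members were listed at 0 in WT libraries. Type II markers were not called without WT replicate 8 or 10 (adjusted p = 0.0604 and 0.0676), after quantile normalization (0.099) or in the fit of all 10 groups (0.0608). T cell markers were not called without tumour replicate 9 or 10 or WT replicate 9 (0.0812, 0.0939 and 0.688) or in the fit of all 10 groups (0.0963), and ciliated cell markers without tumour replicate 9 or 11 or WT replicate 9 (0.138, 0.266 and 0.591) or in 4 further alternatives (0.0508 to 0.173). The T and ciliated lists had an adjusted p = 0.727 and an adjusted p = 0.735 with an estimated correlation. Adjusted over the list alone, 10 type II markers, 8 type I markers and 5 MHC class II genes were lower.

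**Figure D1:**
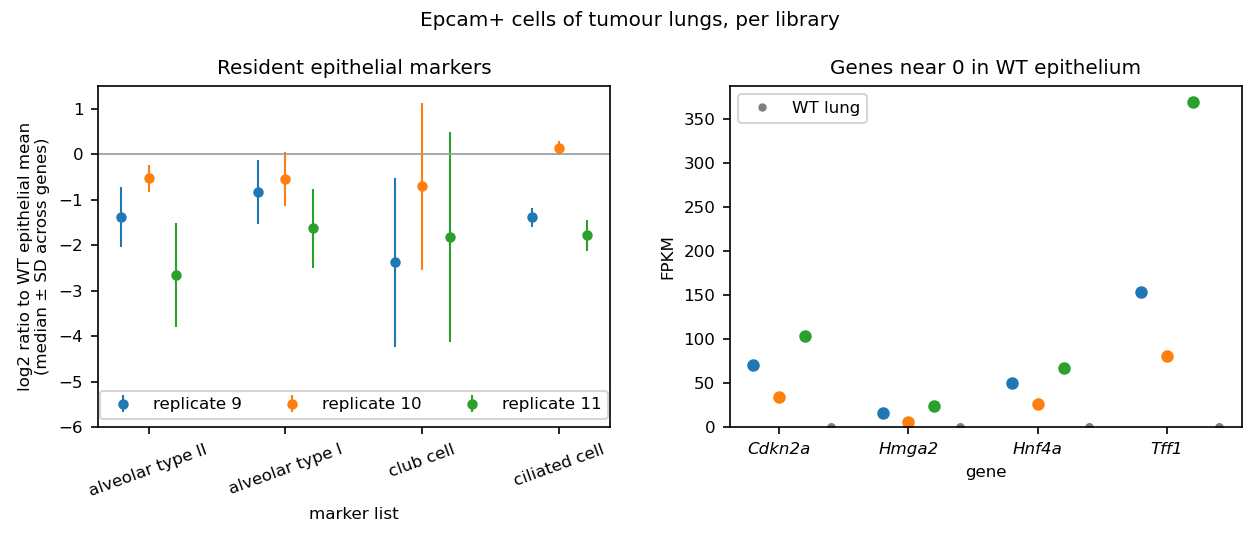
Left, median log2 ratio to the WT epithelial mean of 4 sets of resident cell markers in each tumour epithelial library (bars are SD across genes); right, FPKM of Cdkn2a, Hmga2, Hnf4a and Tff1 in each library, with WT libraries in grey. Alveolar type II markers and the tumour genes moved in opposite directions across replicates 9, 10 and 11, with Cdkn2a at 70.7, 34.8 and 103 FPKM.

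Total lung cells, with no sort, showed more macrophage and neutrophil transcripts and fewer transcripts of alveolar epithelium, endothelium, B cells and NK cells. Il23a rose from 0.327 ± 0.115 FPKM in WT to 104 ± 38.9 in tumour libraries (mean ± SD, n = 3 each) and Spp1 from 28.1 ± 8.61 to 2089.6 ± 708. The lipid receptor gene Trem2 rose from 5.10 ± 0.355 to 109 ± 36.9 FPKM, and Cxcl2, a neutrophil attractant, from 352 ± 28.6 to 5245 ± 1909.8. Sftpa1, a surfactant protein gene, fell from 1039 ± 294 to 76.2 ± 91.1 FPKM, and Sftpb from 1606 ± 485 to 159 ± 167. Gzma, a granzyme of NK cells, fell from 347 ± 43.1 to 104 ± 34.9.

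In total lung cells limma called 2599 genes higher and 2394 lower of 11747, against 2411 and 2660 after upper-quartile scaling. Il23a changed by 6.23 on the log2 scale (SE 0.28, adjusted p = 2.58e-05), Spp1 by 6.14, Il1a by 5.64, Tff1 by 5.49 and Lgals2 by 5.47. Inmt (-4.66), Sftpa1 (-4.43) and the chitinase gene Chia (-4.11) fell furthest. Sftpc, Ddx39b and Hspa1a were listed at 0 in WT libraries. By camera, 14 of 38 lists rose and 7 fell, and with an estimated correlation each had an adjusted p of 0.344 to 0.532.

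Immune regulation genes rose in 18 of 22 members of the total lung (median log2 change 2.04, adjusted p = 8.36e-09), with the glycoprotein gene Gpnmb going from 5.65 ± 1.74 to 195 ± 64.1 FPKM. Monocyte-derived macrophage markers rose in 16 of 20 (adjusted p = 2.82e-08), alveolar macrophage markers in 15 of 18 (adjusted p = 3.93e-05) and mature neutrophil markers in 15 of 16 (median 2.17, adjusted p = 1.03e-06). Sorted tumour macrophages had lower alveolar macrophage markers, and the source of their rise in total lung was not tested. Inflammatory mediators rose in 17 of 21 members (adjusted p = 9.82e-08), chemokines in 16 of 23 (5.68e-05) and matrix proteases in 20 of 26 (9.80e-05). Oxidative phosphorylation rose in 20 of 28, glycolysis in 14 of 18 and cell cycle in 25 of 39, at adjusted p values of 1.99e-06, 4.47e-06 and 4.47e-06. Mesenchymal transition genes rose in 13 of 22 members, lipid uptake and storage in 14 of 21, phagocyte oxidase and antimicrobial genes in 7 of 12 and p53 target genes in 10 of 18 (adjusted p = 0.00181, 0.00999, 0.0119 and 0.0284). Cdkn1a, the p53 target that encodes the inhibitor p21, went from 43.5 ± 5.63 to 214 ± 55.9 FPKM. The p53 call ended when only genes of at least 5 FPKM were kept (adjusted p = 0.137) or a replicate block was added (adjusted p = 0.0765), and the oxidase call after quantile normalization (adjusted p = 0.062). Interferon-stimulated genes did not pass (24 members, median log2 change 0.22, adjusted p = 0.251).

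Endothelial markers fell in 19 of 19 members of the total lung (median log2 change -2.31, adjusted p = 1.30e-08), alveolar type II markers in 15 of 16 (-2.61, 7.05e-06) and B cell markers in 12 of 12 (-1.94, 1.25e-05). Matrix and fibroblast genes fell in 14 of 25 members, NK cell markers in 9 of 11, alveolar type I markers in 8 of 14 and ciliated cell markers in 6 of 11, at adjusted p values of 0.000135, 0.000482, 0.00246 and 0.00686. T cell markers did not pass (5 of 16 members lower, median -0.17, adjusted p = 0.202). Cd79a went from 481 ± 135 to 120.0 ± 58.5 FPKM and the fibroblast proteoglycan gene Dcn from 302 ± 148 to 22.2 ± 6.12. Adjusted over the list alone, 19 immune regulation genes, 15 mature neutrophil markers and 26 cell cycle genes were higher, and 19 endothelial, 15 type II and 12 B cell markers were lower.

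**Figure D2:**
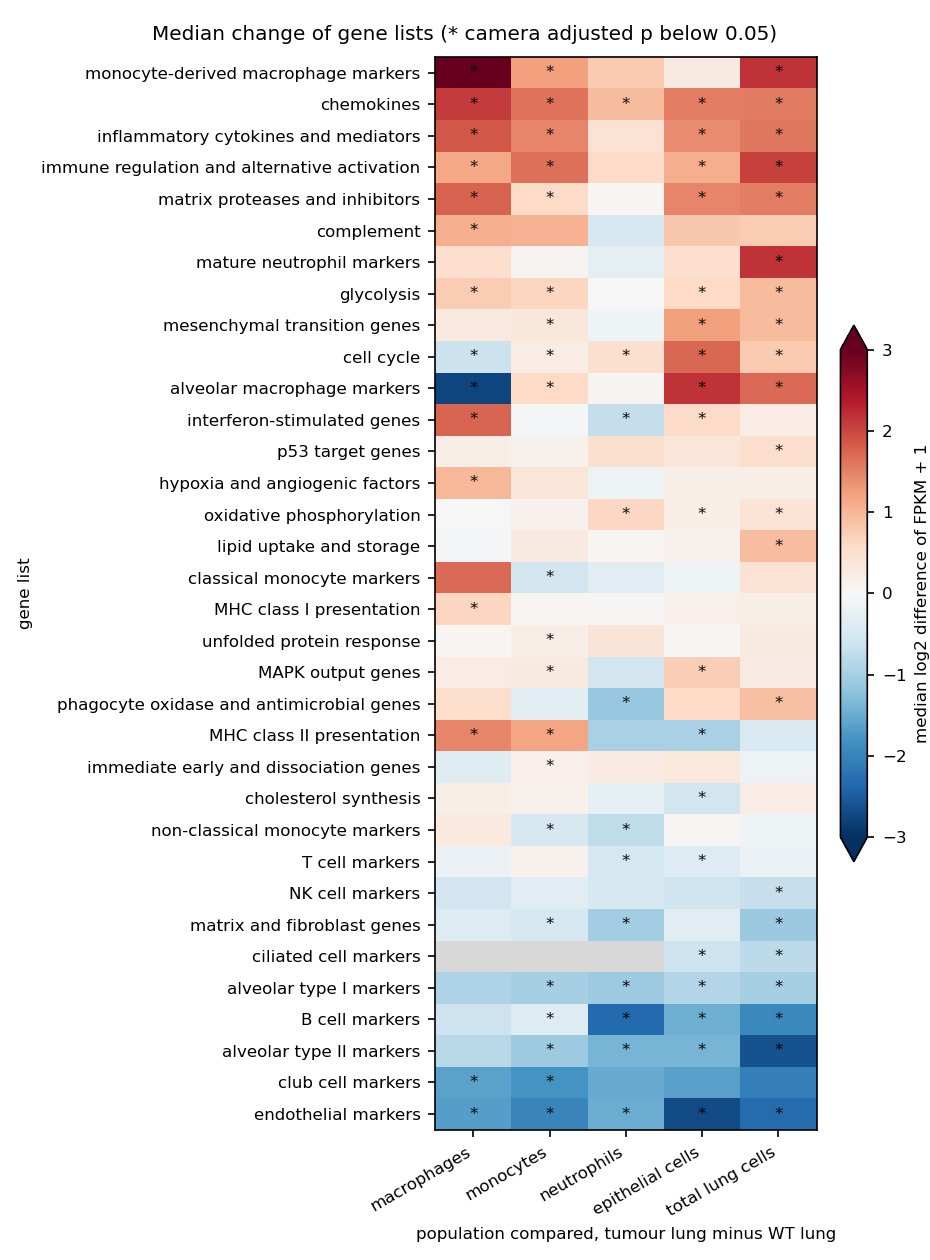
Median log2 change, tumour minus WT, of each fixed gene list in each of the 5 preparations, with colour giving the median and marks giving the camera call at its preset correlation. Endothelial markers were lower in all 5, whereas interferon-stimulated genes had a median of 1.75 in macrophages and -0.72 in neutrophils.

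The next comparison asked whether tumour lung had a different effect in one myeloid population than in another. Contrasts with macrophages also hold the difference in CD11b between the tumour and WT gates. Interferon-stimulated genes moved apart: Rsad2 went from 0.219 ± 0.0281 to 83.6 ± 15.5 FPKM in macrophages and from 99.2 ± 16.7 to 23.9 ± 10.9 in neutrophils, a difference in log2 change of 8.21. Pla2g7 also rose in macrophages, from 1.67 ± 1.48 to 217 ± 52.1 FPKM, and stood at 562 ± 51.4 in WT and 215 ± 23.6 in tumour neutrophils (difference 7.83). Ltc4s moved the other way, from 265 ± 23.7 to 33.5 ± 7.79 FPKM in macrophages and from 2.41 ± 0.889 to 145 ± 25.1 in neutrophils (difference -8.41). Spp1 was at 275 ± 43.9 FPKM in WT and 251 ± 40.2 in tumour neutrophils, and its change was 4.95 larger in monocytes.

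Limma's interaction term called 5627 of 10669 genes between macrophages and neutrophils, 1664 of 10857 between macrophages and monocytes and 2021 of 10738 between monocytes and neutrophils. In the last pair 914 differences were positive and 1107 negative, against 812 and 800 after quantile normalization and 1159 and 817 after upper-quartile scaling. Between macrophages and monocytes 909 were positive and 755 negative, against 851 and 899, and 831 and 912. The count for macrophages and monocytes fell to 773 without WT macrophage replicate 1 and to 746 without WT macrophage replicate 2. That for monocytes and neutrophils fell to 1283 without tumour monocyte replicate 4, to 1316 without tumour neutrophil replicate 6 and to 1319 without tumour neutrophil replicate 8.

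Tested on the interaction, a step chosen after the single comparisons were seen, the interferon-stimulated list differed by a median of 2.63 between macrophages and neutrophils (24 members, adjusted p = 2.94e-10; adjusted p = 0.360 with an estimated correlation). Between macrophages and monocytes it differed by 2.16 (25 members, adjusted p = 1.75e-14; adjusted p = 0.364 with an estimated correlation). The alveolar macrophage list differed by -2.64 and -3.52 (adjusted p = 0.216 and 0.120 with an estimated correlation). For every list, the contrasts with macrophages were joined to the CD11b gate. Monocyte-derived macrophage markers differed by 3.01 and 2.48 (0.273 and 0.492 with an estimated correlation). MHC class II differed by 1.97 between macrophages and neutrophils (adjusted p = 0.00205; adjusted p = 0.478 with an estimated correlation) and by 1.70 between monocytes and neutrophils (adjusted p = 9.58e-06; adjusted p = 0.769 with an estimated correlation). B cell markers moved with it, by 1.67 and 1.98 (adjusted p = 0.00505 and 1.14e-05; adjusted p = 0.478 and 0.769 with an estimated correlation).

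**Figure D3:**
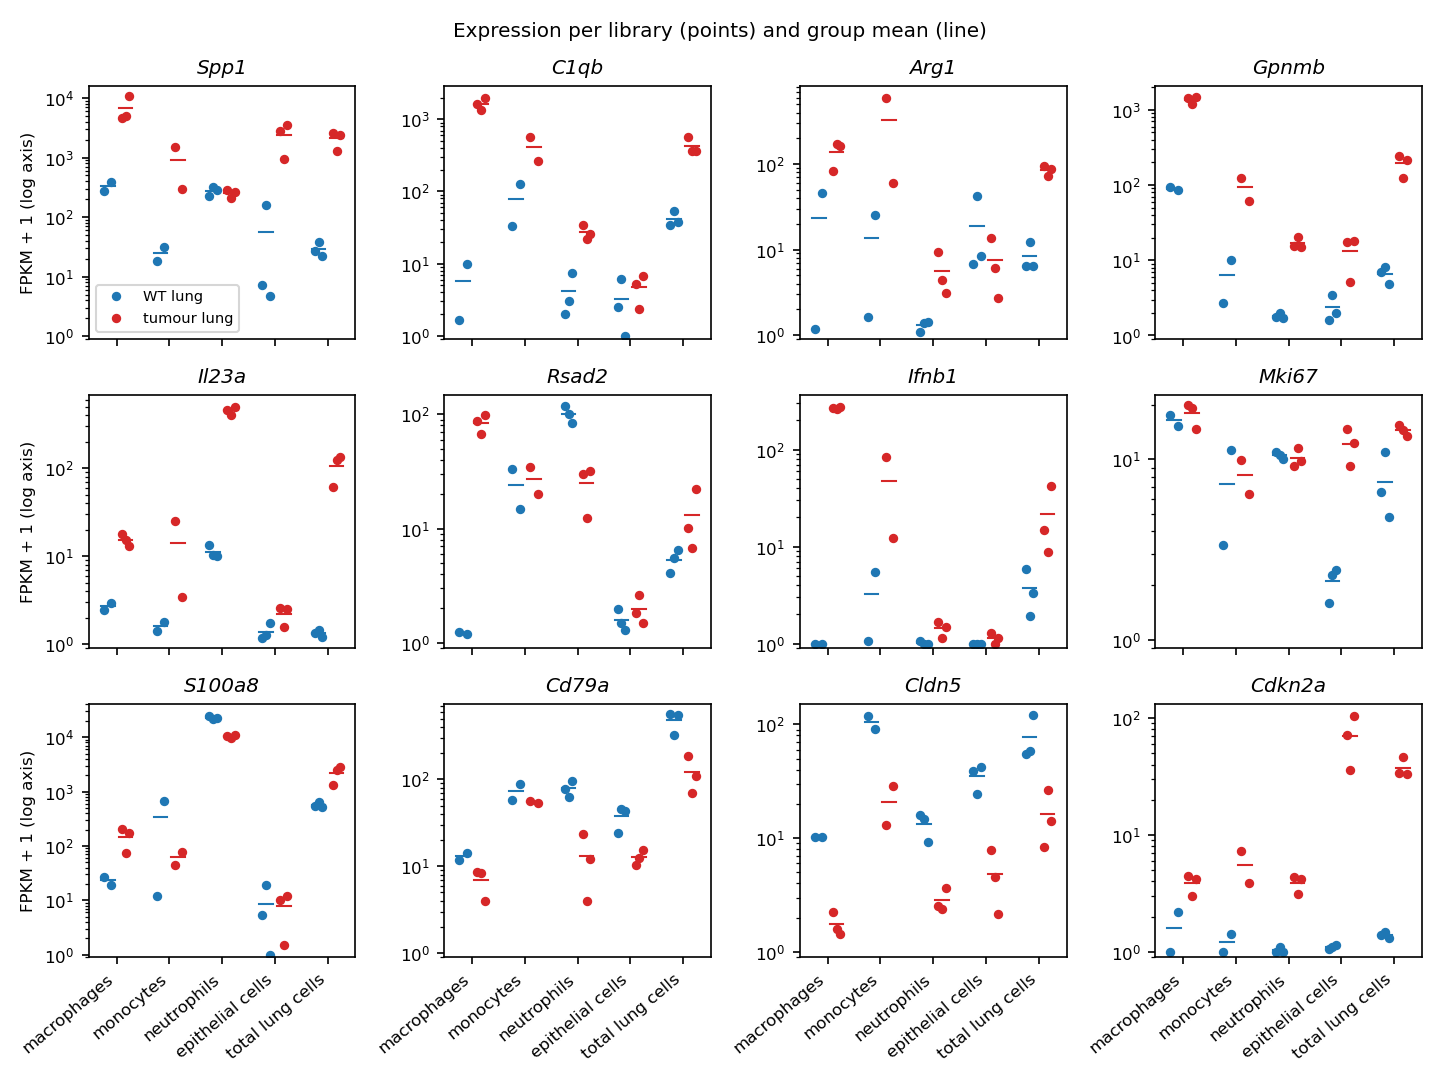
FPKM + 1 on a log axis of 12 genes in each library of the 10 groups, with points for libraries and a line at each group mean. Rsad2 is higher in tumour than in WT macrophages and lower in tumour than in WT neutrophils, and Spp1 reaches a mean of 6811 FPKM in tumour macrophages.

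Calls were then compared across preparations, which share no library. Epithelial and total lung cells shared 997 genes higher in tumour, where independent lists of these sizes give 368, and 619 lower, where they give 199.6. Neutrophils and total lung shared 1099 higher and 845 lower, against 736 and 405. Macrophages and total lung shared 757 and 402, against 477 and 275. Macrophages and neutrophils shared 488 genes lower, against 349 (exact hypergeometric adjusted p = 1.79e-19), and 520 higher, fewer than the 617 of independent lists. With no gene called in monocytes by limma, none was called in all 3 myeloid populations. A fit of all 10 groups with a shared spread per gene called 123 genes higher and 93 lower in all 3, where independent lists give 33.1 and 12. On simulated data, 172 of the 335 genes that fit called in monocytes were false. Its shared genes with the largest mean rise were C1qb, C1qc and C1qa, Syngr1, AA467197, Gpnmb, Il1a and Il23a. Those with the largest mean fall were Sftpc, Sftpb, Egfl7, Plvap and Cldn5, genes of alveolar type II cells and endothelium. C1qb averaged 1654 FPKM in tumour macrophages and 414 in tumour monocytes. Whether RNA of other cells in the sorted samples made up part of these shared changes was not tested for all 3 populations.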

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

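The tests of explanations in this part were all chosen after the results were seen, while the interaction terms were planned.

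The effect of tumour lung differed between myeloid populations by the interaction term: 1664 genes between macrophages and monocytes, 5627 between macrophages and neutrophils and 2021 between monocytes and neutrophils. Every contrast with macrophages also carries the CD11b difference between their gates. Between macrophages and monocytes the differences in log2 change among genes of the naming rule included 6.88 for Pla2g7 (adjusted p = 0.000122), 6.09 for C1qb, 5.86 for Rsad2 and 5.82 for Hpse. Pla2g7 averaged 115 FPKM in WT and 88.2 in tumour monocytes, and Rsad2 23 and 26.3. On the other side stood Krt19 (-8.05), which went from 382 to 9.88 FPKM in macrophages and from 1.30 to 16.1 in monocytes, and Cidec (-6.35), which was listed at 0 in WT monocytes and averaged 0.256 FPKM in tumour monocytes, so nearly all of its difference is the fall in macrophages.

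Between macrophages and neutrophils the differences were 8.21 for Rsad2, 7.83 for Pla2g7 and -8.41 for Ltc4s (adjusted p = 1.24e-07, 5.50e-08 and 5.18e-09). Between monocytes and neutrophils they were 4.95 for Spp1, 4.49 for Pdpn, -4.12 for Car4 and -4.47 for Ltc4s (adjusted p = 0.0031, 0.00151, 0.00113 and 0.0046). Pdpn went from 1.06 to 24.6 FPKM in monocytes and from 9.42 to 3.81 in neutrophils. The naming rule also picked 3, 7 and 6 genes in the 3 contrasts for which a group was listed at 0 while the other group of that population averaged at least 5 FPKM, and these carry no difference. On simulated data, 39 of 163 calls between macrophages and monocytes and 51 of 185 between monocytes and neutrophils were false.

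Of the 10 splits of the 6 neutrophil libraries into 3 and 3, only 1, the real one, gave as many genes as the 5524 called, and the highest other gave 0. In epithelial cells 1 of 10 gave 2816 with 0 as the highest other, and in total lung cells 1 of 10 gave 4993 with 0 as the highest other. With 10 splits the share cannot fall under 0.05. Every other split has tumour and WT libraries on both sides, so a tumour difference widens its spread. Their counts of 0 therefore add nothing beyond that share.

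Abundant genes listed at 0 in every library of a group formed the first of 3 patterns weighed. Silence was argued against for Sftpc, listed at 0 in WT total lung, since WT neutrophils sorted from such lungs carried it at a mean of 968 FPKM. Loci with very many fragments that were given no estimate may account for part: of 17 such genes, 10 ranked within the first 10 by FPKM times transcript length in the other group, where 0.539 were expected. Sftpc, ranked 95, is not among them. That rank was taken in tumour total lung, where the surfactant gene Sftpb averaged 159 FPKM against 1606 in WT. The rank of Sftpc in WT lung is therefore unknown. Other type II genes were far lower in WT neutrophils than in WT total lung: Sftpa1 averaged 60.2 against 1039 FPKM and Sftpb 90.4 against 1606. If Sftpc followed them, its level in WT total lung lay well above the 968 FPKM of WT neutrophils. It was listed at 0 in 9 libraries in all, and a missing estimate stays open for its value of 0. Ifnb1, ranked 337 of 353, is not among them either, and silence in WT macrophages stays open for it. For S100a9 and Il1b in neutrophils, ranked 3 in their groups, the values of 0 say nothing about tumour against WT.

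The second pattern was the fall of alveolar and endothelial transcripts in sorted neutrophils. RNA or cells of lung tissue in the sorted samples may be their source: across 34 marker genes, levels in WT neutrophils followed those in WT total lung (Spearman rho 0.883 across genes, which are not independent), at a median of 11.3% of the total lung level. The log2 ratio had an SD of 0.73 across genes, under the 1 set for levels unrelated to those in total lung, which argues against transcription by the WT neutrophils themselves. In tumour lung rho was 0.65 over 35 genes, under the 0.7 set for a match, so the source of what remained there stays open. The ratio of Sftpa1 to Sftpb was 0.648 to 0.705 in WT neutrophils and 0.647 in WT total lung. Tumour total lung itself held a smaller share of these transcripts: endothelial markers fell there in 19 of 19 members and alveolar type II markers in 15 of 16. Whether less tissue RNA was also carried stays open, and a biological difference in the neutrophils was not tested.

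The third pattern was a trade between alveolar type II markers and genes absent from WT epithelium across the tumour epithelial libraries. Type II markers had lost 61.4%, 30.5% and 84.0% of their WT level in replicates 9, 10 and 11. If HKP1 cells replaced that share, 27 tumour-only genes should differ between replicates 10 and 11 by -1.46 on the log2 scale, and they differed by a median of -1.57 (SD 0.36). The largest gap between predicted and observed over the 3 pairs was 0.112. Type I markers had lost 43.8%, 31.6% and 67.6%, and the same prediction from them missed by 0.475 between replicates 10 and 11 (SD 0.36) and by 0.525 between replicates 10 and 9 (SD 0.28). Ciliated markers stood at 110% of WT in replicate 10. A mixture of HKP1 cells and resident epithelium therefore stays open, as do resident cells that changed state. Trp53, which HKP1 cells lack as a protein, stood at 12.6 FPKM against 17.6 in WT and was not called, and whether HKP1 cells make its transcript was not tested. Equal dilution of all resident epithelial types stays open: the ciliated median lay 0.665 above the type II median in replicate 10 (combined SD 0.339). The gap was within its SD in replicate 9 (0.00565, SD 0.689) and replicate 11 (0.869, SD 1.20). That SD is the spread of single genes and not the error of a median, so a gap within it does not speak for equal dilution.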

How the results depend on the processing

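Leaving out genes listed at 0, and leaving out genes far higher in another population, were chosen after seeing the data; the other alternatives were planned. Of 441 recomputed counts and list totals, 389 stayed within 1.5 times the reported one and 52 moved further. The cause was not tested unless stated.

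With an estimated correlation, 0 lists were called higher and 0 lower in macrophages, monocytes, neutrophils, epithelial cells and total lung cells. On simulated data that setting also missed shifted lists in 3 of the 5. The simulated genes were uncorrelated, so this does not decide which correlation setting is right for the real lists. The fit of all 10 groups called 540 genes higher and 612 lower in monocytes, 2974 and 2369 in epithelial cells and 123 and 93 in all 3 myeloid populations. It gives each gene one spread for all groups, and on simulated data 172 of 335 calls in monocytes and 222 of 413 in epithelial cells were false. It left 3 lists lower in monocytes and 1 higher in neutrophils. Quantile normalization raised the latter to 6. A filter of 5 FPKM left 5 lists lower in monocytes, as did leaving out genes far higher in another population. Without a filter, 647 genes were lower in epithelial cells.

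Replicate numbers ran in order through all tumour and all WT libraries, so equal numbers need not denote a pair, and no block was used. Across genes, r between libraries of the same number ranged from -0.17 to 0.0816. Between unlike numbers it ranged from -0.205 to 0.178. With so few libraries per group, these values cannot exclude that samples were paired. A block left 1904 genes higher in neutrophils, 307 higher and 90 lower in epithelial cells, and 1285 higher and 1138 lower in total lung cells, with fewer degrees of freedom.

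Leaving out each library in turn gave these ranges, with a lone library assumed to vary like the others. Macrophages had 1105 to 2390 genes higher and 673 to 2130 lower, and monocytes 0 to 161 and 0 to 149, with the highest counts without tumour replicate 5. Neutrophils had 2542 to 2988 and 2096 to 2296, epithelial cells 386 to 2420 and 104 to 1795, and total lung cells 1901 to 2540 and 1630 to 2179. Lists lower in monocytes numbered 5 to 8. Interactions numbered 746 to 1758 for macrophages and monocytes, 4445 to 5709 for macrophages and neutrophils and 1283 to 1939 for monocytes and neutrophils. Genes shared by all 3 myeloid populations numbered 0 to 55 higher and 0 to 78 lower. The fewest in macrophages came without a WT replicate, where 1 library remained.

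Itgam in neutrophils reversed to 0.38 under quantile normalization (adjusted p = 0.0472), from -0.02. The cell cycle list reversed in monocytes without WT replicate 3 (adjusted p = 0.00826, with adjusted p from 1.04e-12 to 0.0874 over the 4 libraries left out) and in neutrophils with the filter of 5 FPKM (adjusted p = 0.978). Of the genes named by rule, 1346 of 1502 values kept their call with 1 library left out, 136 lost it, 10 gained one and 10 moved. Named lists kept theirs in 434 of 471. Of the interaction genes picked by rule, 3, 7 and 6 in the 3 contrasts had a group listed at 0 and carry no difference. The remaining 14 kept their call under every alternative run. They were picked as the largest differences, so this says little about the other interaction calls.

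Groups did not overlap for 63.7% of genes in macrophages (20% by chance), 48.2% in monocytes (33.3%), 66.3% in neutrophils (10%), 46.5% in epithelial cells (10%) and 55.8% in total lung cells (10%). Depth in counts is unknown, so no floor is given for low FPKM.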

Other observations

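The genes in this part were chosen after their values were seen. Several genes under 1 FPKM in WT epithelium were higher in tumour epithelial libraries. Hnf4a, a transcription factor on chromosome 2 of GRCm38 from 163506808 to 163572910, averaged 48.1 ± 20.5 FPKM against 0.174 ± 0.203 in WT (mean ± SD, n = 3 each, log2 change 5.30). It was at 50.2, 26.7 and 67.5 FPKM in replicates 9, 10 and 11. The homeobox gene Cdx2 averaged 11.2 ± 4.52 against 0.0231 ± 0.0252 FPKM, the keratin gene Krt20 98.8 ± 57.4 FPKM in tumour libraries (log2 change 6.35), and the cadherin gene Cdh17 44.1 ± 21.1 against 0.165 ± 0.112. Sox9 averaged 33.4 ± 12.3 against 0.216 ± 0.255 FPKM. Nkx2-1, the lung lineage factor, stood at 85.0, 146 and 43.0 FPKM in these replicates, below the WT mean by a log2 change of -1.29, and was not called (adjusted p = 0.0525). Gata6 averaged 17.3 against 17.0 FPKM.

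Ifnb1 lies on chromosome 4 from 88522025 to 88522774. It was at 82.5 and 11.3 FPKM in the tumour monocyte libraries and at 7.70 to 40.7 FPKM in tumour total lung cells.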
